A study of Salamandra salamandra with 24 samples.

How the data were processed

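Total RNA was extracted with Trizol from tail tips and from the remaining bodies of 12 larvae, labelled with Cy3 by the Agilent Low Input Quick Amp kit and hybridised to 24 Agilent arrays of 1 colour, per the labels' protocols. The labels give each array's tissue, temperature and larva. The same numbers 4, 5, 6 and 7 occur among cold and warm larvae, which are separate animals.

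The scanner files were made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers. Per the file headers, the processed signal is a linear intensity per spot, corrected for background and spatial trends within the array and not normalised between arrays; the mean signal and the local background median are uncorrected intensities. The value table deposited by the authors holds a linear ratio for 14910 of the 22145 probes, already averaged over spots. In every column its 75th percentile is 1, and the median is between 0.214 and 0.235 on 23 arrays and 0 on that of warm body replicate 3. On a log scale it correlated with the scanner values of the same array at r from 0.992 to 0.999, and at 0.58 for that array, whose column held 7170 zeros. The step that made the table and its filter are not given in the sources used here. Its scale (relative to the 75th percentile) and direction are settled by this comparison, and it was used as an alternative only.

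Spots of control probes and spots flagged as outliers were left out, and saturated spots were kept. The log2 processed signals of the 2, 3 or 10 spots of a probe were averaged, and the 75th percentile over the probes of the array was subtracted. A value of 0 is thus the array's 75th percentile. A probe was tested where it was well above background, on most of its spots, on at least 4 of the 6 arrays of at least 1 group in the fit. Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05 on the adjusted p. No minimum fold change was set.

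Temperature (warm minus cold) was tested separately in the 12 body and the 12 tail arrays. The difference between tissues (body minus tail) and the difference of the temperature responses (body less tail) were tested on all 24 arrays with the larva as a fixed block, since the design text states that both samples came from the same animals. This pairing was checked by the correlation, across 14807 probes, of a larva's body and tail deviations from their group means: its mean was 0.43, and the highest mean over 100 pairings of different larvae was 0.05. The rule for named genes, fixed at the start, took the largest changes among genes with a name in the files; where no name can be had, it allowed at most 2 probes that rose and 2 that fell per comparison. The named probes are therefore the 2 with the largest positive and the 2 with the largest negative log2 fold change past the threshold, 1 per distinct sequence. Where a named probe was not well above background, its lower group's value on such arrays was raised to the array's background limit, the 95th percentile of the probes not well above background, unless it was higher already. Sizes given as at least a value were computed this way, with the dim array left out for temperature in body and its larva for the difference of responses. These limits, the opposite calls, the classes by tissue of higher signal and the covariance of the responses were added after values were seen. Gene lists had been prepared before the data were examined; the files give no gene names, so they were not used. Of the 22145 probes, 4467 sequences occur under 2 probe IDs; the fold changes of such pairs correlated at r = 0.97 in body and 0.99 in tail, and the main counts of probes are therefore given with counts of sequences.

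Alternatives comprised other background correction and normalisation (normexp with an offset of 50, quantile normalisation, a median of bright probes), other filters, the authors' value table (with values under 0.05 set to 0.05 before log2), blocks for slide and larva number, array weights and each larva left out. No 2 arrays held identical values, and the highest correlation of 2 arrays was 0.989. The arrays lay on 3 slides of 8, scanned on the same day, and each slide held all 4 groups. The body and tail arrays of each labelled larva lay on different slides, so every difference within a larva was also one between slides. The number of larvae, 6 per group, limits the precision of each value.

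The fits were tested on simulated data made from the means and spreads of 16485 probes, 200 of them changed. For temperature in body, 68% of the changes of 1 on the log2 scale and 86% of those of 2 were recovered, and in tail 88 and 92%. For the difference of responses the shares were 64 and 90%, and for tissue 92 and 100%. The median size of the changes called for temperature in the real data was smaller, 0.56 in body and 0.51 in tail. Of simulated changes of 0.5, 16% were recovered in body, 30% in tail, 8% for the difference of responses and 58% for tissue. False calls numbered 8 of 141, 8 of 161, 19 of 148 and 14 of 189 calls, in that order.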

Results

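Gene expression was measured in 12 larvae of the fire salamander, Salamandra salamandra, an amphibian whose larvae develop in streams and ponds. Of these larvae, 6 had been exposed to 9 °C (cold) and 6 to 17 °C (warm). Each larva gave a sample from the tip of its tail and a sample from the rest of its body, so that there were 4 groups of 6 arrays: cold body, warm body, cold tail and warm tail. The design text names the purpose: a tail tip can be taken from a living animal, and the temperature response seen in it was to be set against that of the body. The array carried 22145 probes of 60 bases, with 17678 distinct sequences, and each probe was designed on an open reading frame of an assembled contig. The files pair no probe with a gene name, so transcripts are given by probe and contig.

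On 23 of the 24 arrays the 75th percentile of the processed signal lay between 283.5 and 447 intensity units, and between 70.2 and 77.3% of the spots were well above background. The array of warm body replicate 3 was far dimmer, with a 75th percentile of 15.9 and 28.8% of its spots well above background. It was kept in the comparisons, and the counts and named probes of the body and of the difference of responses are also given without it. The first principal component held 71.7% of the variance and separated body from tail. The second held 7.41%, mostly the distance of the dim array from the others. The third held 4.57%, and along it all 12 cold arrays lay above 0 and 11 of the 12 warm arrays below 0, the dim array being the exception.

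**Figure D1:**
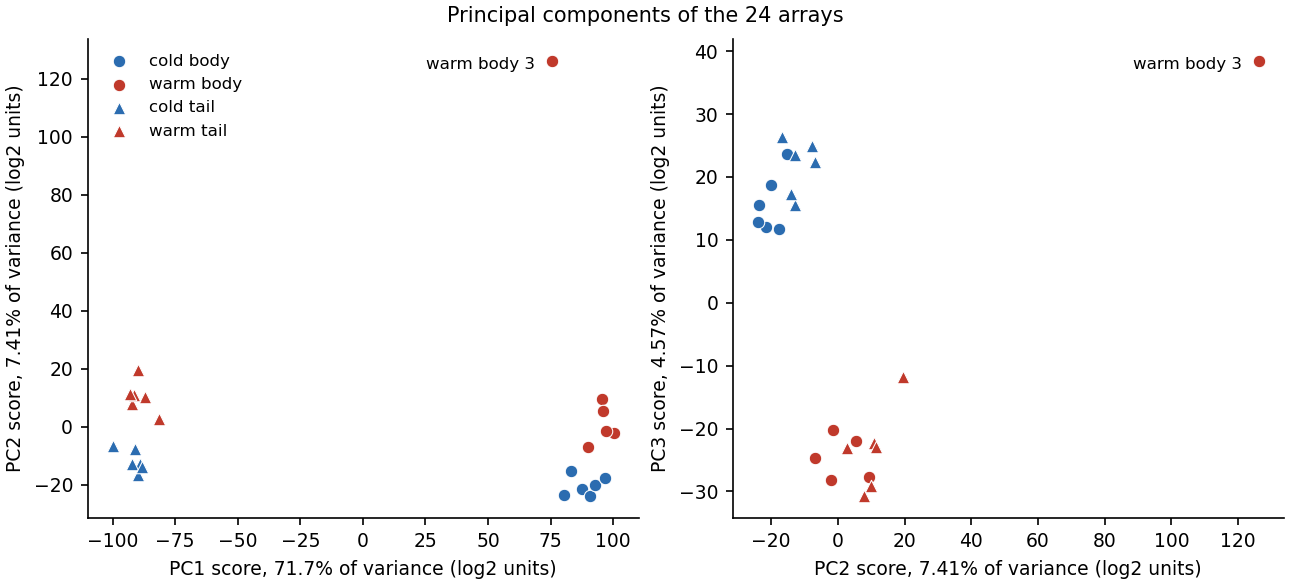
Principal component scores of the 24 arrays (log2 units; blue circles cold body, red circles warm body, blue triangles cold tail, red triangles warm tail). The first component (71.7% of the variance) parts body from tail, the third (4.57%) parts the cold arrays from 11 of the 12 warm ones, and warm body replicate 3 lies on the cold side of the third and alone on the second (7.41%).

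In the body, temperature changed the signal of 2567 of the 15653 probes tested, 1256 of them higher and 1311 lower at 17 °C than at 9 °C (limma, adjusted p under 0.05). These probes stood for 1988 distinct sequences. The median size of the change among them was 1.47-fold; 227 probes rose and 78 fell by at least 2-fold, and 16 rose and 5 fell by at least 4-fold. Without the dim array 189 rose and 117 fell by at least 2-fold, and 18 and 8 by at least 4-fold. The largest fitted rise was that of KUST_30063_PI429357568 (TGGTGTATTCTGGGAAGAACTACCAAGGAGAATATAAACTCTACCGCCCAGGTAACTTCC), designed on the reading frame at bases 206 to 727 of contig comp390685_c0_seq1. Its log2 level relative to the array's 75th percentile was -5.98 ± 1.44 (SD, n = 6) in cold and -2.10 ± 1.91 (SD, n = 6) in warm bodies. Its log2 fold change was 3.88 with a standard error of 0.86 (adjusted p = 0.00825), and 4 of the 5 warm bodies other than the dim array lay above every cold body. It was well above background on only 2 of the 6 cold body arrays, on 5 of the 6 warm body arrays and on none of the 12 tail arrays; the 1 warm body array at background was the dim one, which cannot be ranked against the cold bodies. With the cold arrays at background set to their background limit and the dim array left out, the rise was at least 2.82 on the log2 scale. KUST_5708_PI429357568 (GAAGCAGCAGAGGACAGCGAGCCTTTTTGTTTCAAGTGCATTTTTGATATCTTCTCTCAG; bases 17 to 565 of comp1853662_c0_seq1) rose from -5.23 ± 1.08 to -2.22 ± 1.62 (SD, n = 6 each), a log2 fold change of 3.01 with a standard error of 0.70 (adjusted p = 0.011), and 4 of the 5 warm bodies other than the dim array lay above every cold body. It too was at background on the dim array and well above background on only 2 of the 6 cold bodies, and with the same limits its rise was at least 2.58.

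The largest fitted fall in the body was that of KUST_33950_PI429357568 (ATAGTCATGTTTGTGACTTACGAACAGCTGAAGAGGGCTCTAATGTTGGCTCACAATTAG; bases 980 to 1891 of comp400824_c0_seq1). Its level was -0.09 ± 1.49 in cold and -3.96 ± 1.17 in warm bodies (SD, n = 6 each), a log2 fold change of -3.87 with a standard error of 0.68 (adjusted p = 0.00214), and the measured values of all 6 warm bodies lay below those of every cold body. It was well above background on only 2 of the 6 warm bodies. On the dim array its value of -1.77 lay under that array's background limit of -0.61, so that this body cannot be ranked against the cold ones. KUST_23171_PI429357585 (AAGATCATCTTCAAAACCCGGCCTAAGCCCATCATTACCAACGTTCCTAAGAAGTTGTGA; bases 1785 to 2165 of comp142221_c0_seq1) fell by 2.45 on the log2 scale, with a standard error of 0.55 (adjusted p = 0.00857), and 4 of the 5 warm bodies other than the dim array lay below every cold body. On the dim array its value of -2.41 was also under the background limit and cannot be ranked. The cold larva 6 was an exception for this probe, at -2.72 in its body and -2.26 in its tail, while the other cold bodies lay between -0.06 and 0.11. The 4 probes changed in the same direction within each of the 3 slides that held the arrays. They had been chosen as the largest changes over these same arrays, so this is not separate support. Over the alternative normalisations and without a filter, the adjusted p of KUST_30063_PI429357568 ranged from 0.00866 to 0.0928 and that of KUST_5708_PI429357568 from 0.012 to 0.112. The first missed the threshold under quantile normalisation (adjusted p = 0.0556), where its log2 fold change was 3.17. Both missed it under background correction by normexp followed by quantile normalisation, where their log2 fold changes were 1.13 and 0.93. Without the dim array the log2 fold changes of the 4 probes, in the order named, were 3.96, 3.03, -4.31 and -2.55 (adjusted p = 0.0105, 0.0147, 0.000637 and 0.00997).

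Without the dim array the number of probes changed in the body was 3915, of which 1885 were higher and 2030 lower at 17 °C, and 2517 of the 2567 were among them. Quantile normalisation moved the median log2 fold change of all probes tested in the body from 0.07 to -0.08, and gave 826 higher and 1198 lower; normexp with quantile normalisation gave 675 higher and 1136 lower. With the slide as a block, 2023 probes passed. Within slides 1, 2 and 3, where cold and warm bodies numbered 3 and 1, 1 and 2, and 2 and 3, the probes called on the other slides alone had the same direction for 96.5, 83.8 and 99.2%. Those probes numbered 723, 2879 and 120, so the last share rests on few. The fold changes of a slide correlated with those of the other slides at only r = 0.44, 0.37 and 0.47. Slide 2 held the dim array.

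In the tail tip, temperature changed 3750 of 15873 probes tested, 2056 higher and 1694 lower at 17 °C (limma, adjusted p under 0.05), which stood for 2825 distinct sequences. The median size of the change was 1.43-fold among them; 243 rose and 144 fell by at least 2-fold. KUST_46803_PI429357568 (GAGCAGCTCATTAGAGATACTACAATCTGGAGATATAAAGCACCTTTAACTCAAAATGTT; bases 62 to 1369 of comp421676_c0_seq10) had the largest fitted rise, from -4.98 ± 0.91 to -1.69 ± 0.83 (SD, n = 6 each). Its log2 fold change was 3.28 with a standard error of 0.45 (adjusted p = 0.000338), and all 6 warm tails lay above every cold tail. It was well above background on 4 of the 6 cold tails, and with the others at their background limit the rise was at least 3.04. KUST_19515_PI429357568 (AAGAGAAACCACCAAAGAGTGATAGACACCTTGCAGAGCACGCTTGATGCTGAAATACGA; bases 2 to 400 of comp344575_c0_seq1) rose from -3.34 ± 0.37 to -0.36 ± 0.37 (SD, n = 6 each), a log2 fold change of 2.98 with a standard error of 0.20 (adjusted p = 2.44e-06), again with all 6 warm tails above every cold tail.

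The largest fall in the tail was that of KUST_44681_PI429357568 (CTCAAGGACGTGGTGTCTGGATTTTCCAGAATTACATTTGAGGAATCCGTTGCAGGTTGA; bases 113 to 1252 of comp418912_c0_seq1), from 1.87 ± 1.37 in cold to -1.83 ± 1.40 in warm tails (SD, n = 6 each). Its log2 fold change was -3.70 with a standard error of 0.71 (adjusted p = 0.00281). In the body the same probe stood at 5.24 ± 0.53 in cold and 5.22 ± 0.38 in warm larvae (SD, n = 6 each), a log2 difference of -0.02 with a standard error of 0.24. The test of the difference between these responses did not pass (3.67 on the log2 scale, adjusted p = 0.0694). KUST_47270_PI429357585 (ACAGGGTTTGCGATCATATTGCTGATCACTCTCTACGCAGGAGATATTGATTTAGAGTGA; bases 639 to 2042 of comp70247_c0_seq1) fell from -2.31 ± 0.91 to -5.59 ± 1.41 (SD, n = 6 each), a log2 fold change of -3.28 with a standard error of 0.61 (adjusted p = 0.00239), and was well above background on only 2 of the 6 warm tail arrays; with the others at their background limit the fall was at least 2.44 in size. For both probes all 6 warm tails lay below every cold tail. The 4 probes had the same direction within each slide, which is not separate support, as they were chosen as the largest changes over these same arrays. Quantile normalisation gave 1757 higher and 1891 lower in the tail, and normexp with quantile normalisation 1713 and 1869. Scaling to the median of bright probes gave 1851 and 1833, so that the excess of rises depended on the scaling. With the slide as a block 3331 tail probes passed. Within slides 1, 2 and 3, where cold and warm tails numbered 2 and 2, 2 and 3, and 2 and 1, probes called on the other slides alone had the same direction for 97.4, 96.8 and 94.1%. Those probes numbered 1448, 955 and 2542, and the fold changes of a slide correlated with those of the other slides at r = 0.57, 0.57 and 0.48.

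**Figure D2:**
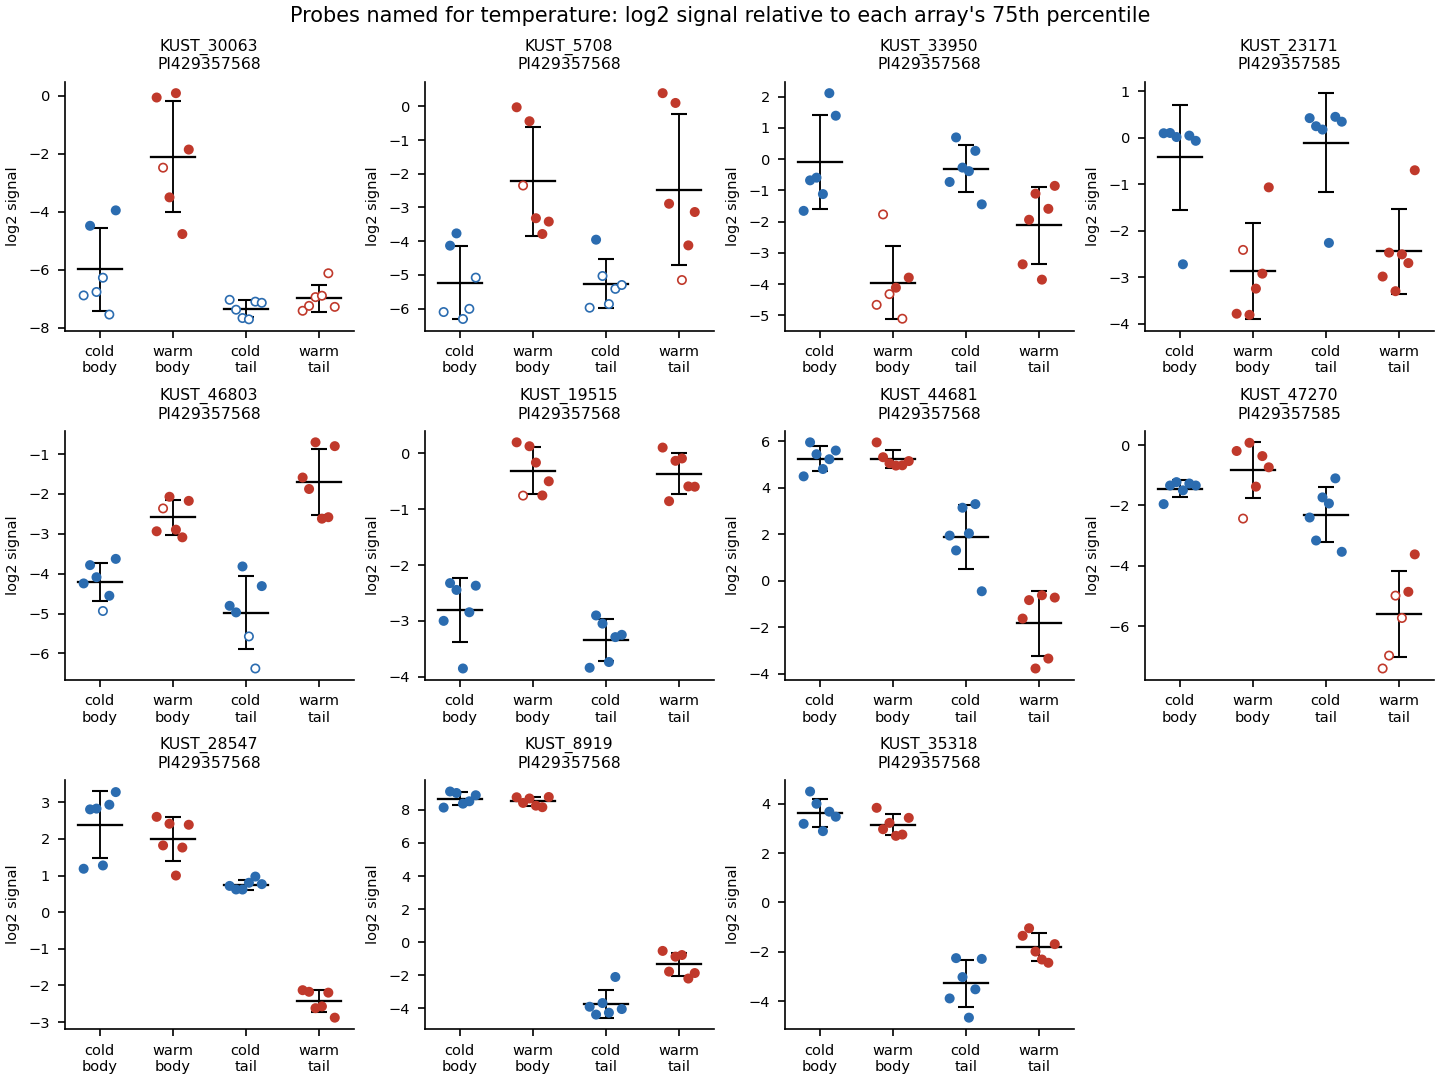
Log2 signal relative to each array's 75th percentile for the 11 probes named for temperature or for a temperature by tissue difference; 1 point per array, filled where the probe was well above background, with the group mean and SD (n = 6). KUST_19515_PI429357568 rose at 17 °C in both tissues, whereas KUST_28547_PI429357568 fell from 0.75 to -2.43 in the tail, with a log2 difference of -0.39 (adjusted p = 0.532) in the body.

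The comparison of the tissues over the 14909 probes tested in both asked how far the tail tip reports the response of the body. Of the 2488 probes called in the body, 2404 (96.6%) had the same direction in the tail and 1625 (65.3%) also passed the test there, 794 higher and 831 lower at 17 °C, with 1241 distinct sequences. Independent lists of these sizes would share 157 higher and 145 lower probes. In the other direction, 44.7% of the 3632 probes called in the tail passed in the body with the same sign, and 2005 were called in the tail only. These shares depended on the dim array's larva. Without warm replicate 3, 55.7% of the body calls passed in the tail and 61.6% of the tail calls in the body. Of all probes tested in both tissues, 2 with the same sequence passed in both in opposite directions. These probes, named after their values were seen, lie on contigs comp373013_c0_seq2 and comp26108_c0_seq1, with log2 fold changes of 0.80 and 0.82 in body and -1.13 and -1.14 in tail. This count was 5 without warm replicate 3, 1 without warm replicate 6, and 0 by limma without cold replicate 2, 4, 6 or 7 or warm replicate 1 or 7, where 13 to 22 probes had an unadjusted p under 0.05 in both tissues with opposite directions (29 with all larvae). Among probes called in both tissues in the same direction, KUST_5708_PI429357568 and KUST_19515_PI429357568 had the largest fitted mean rise (2.90 and 2.74 on the log2 scale), and KUST_33950_PI429357568 and KUST_23171_PI429357585 the largest fitted mean fall (-2.84 and -2.40). KUST_5708_PI429357568 was well above background on 2 of 6 cold bodies and 1 of 6 cold tails, and with background limits in their place its mean rise was at least 2.52. Over all 14909 probes the SD of the log2 fold changes was 0.42 in body and 0.42 in tail.

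Recovery in the tail rose with the size of the fall in the body but not with the size of the rise. Of the probes that fell in the body by under 0.5, by 0.5 to 1 and by 1 or more on the log2 scale, 51.0, 75.3 and 81.9% passed in the tail in the same direction. For probes that rose, the shares were 64.6, 67.8 and 66.5%. Without warm replicate 3 the shares were 41.7, 65.4 and 73.1% for falls and 52.4, 62.8 and 69.2% for rises, so that the flat course of the rises rested on that larva.

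Across probes, which are not independent replicates, the log2 fold changes of body and tail correlated with Pearson's r = 0.70 and Spearman's rho = 0.68, and 76.04% had the same sign. Body and tail came from the same larvae, so 99 other groupings of the 12 larvae into 6 and 6, keeping both arrays of a larva together, were used as a reference. They gave r between 0.18 and 0.70 with a median of 0.45, and 1 of them gave an r as high as the real grouping. That one, which also had the highest share with the same sign (76.32%), put 5 of the 6 cold larvae on the same side. Among the 52 groupings with 3 cold and 3 warm larvae on each side, r was at most 0.59 with a median of 0.39, and at most 68.2% had the same sign. At most 2 probes were called in both tissues in the same direction, against 1625. That difference was fixed in advance, as the other groupings called at most 7 probes in body and 66 in tail. It is no separate evidence that the tissues agree. The covariance of the fold changes, computed in addition to the planned measures, was 0.124 in the real grouping and at most 0.0759 in the others. It grows with the size of the changes as well as with their agreement, so it cannot part the 2. When the body fold change was taken from 3 cold and 3 warm larvae and the tail fold change from the other 3 and 3, r averaged 0.44 over 10 divisions (0.37 to 0.52). With the larvae of body and tail swapped in these divisions r ran from 0.40 to 0.57. With body and tail from the same 3 and 3 larvae, taken as the mean of both sets of a division, it averaged 0.62.

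**Figure D3:**
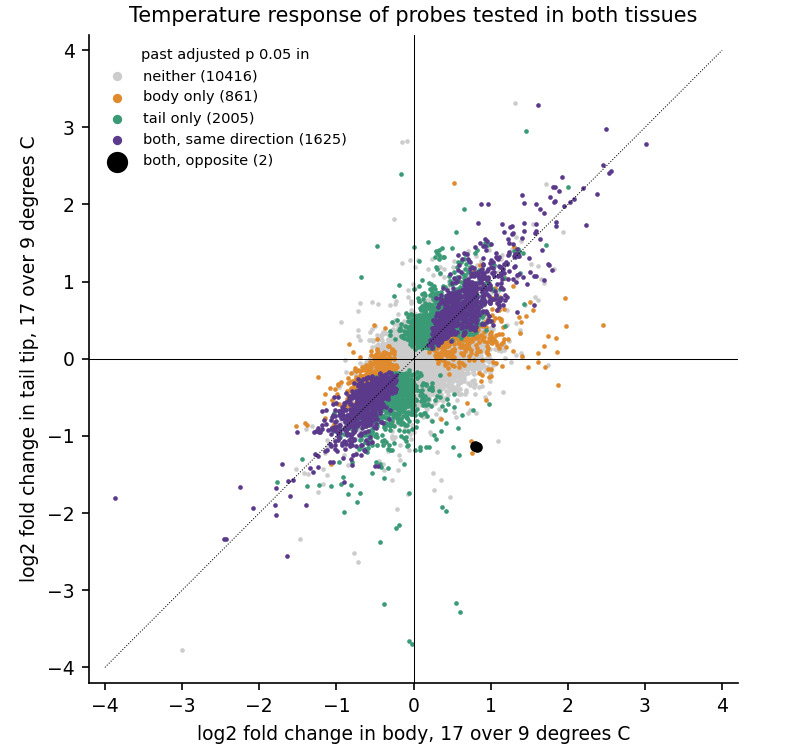
Log2 fold change (17 over 9 °C) in body (x axis) against tail tip (y axis) for the 14909 probes tested in both tissues, coloured by the tissues in which they passed adjusted p 0.05; the dotted line marks equal change. The 1625 probes called in both in the same direction lie along the line, and 2 probes passed in opposite directions.

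Recovery in the tail also differed by the tissue in which a probe was brighter, a division made after the data were seen. Of body calls at least 2-fold higher in body than in tail, 37.1% (79 of 213) passed in the tail in the same direction, against 60.2% (100 of 166) of those at least 2-fold higher in the tail and 68.6% (1446 of 2109) of the rest. With the rest weighted to the same tail levels the last share was 66.6%. The standard error of the tail fold change was also larger for the first class, with a median of 0.25 against 0.11 for the rest. The same 3 classes had correlations of the fold changes of 0.46, 0.71 and 0.74 across probes. Without warm replicate 3 the shares were 29.8, 46.8 and 58.8%. A further 416 probes tested in the body were not well above background on any tail array; 36 of them rose and 12 fell in the body at 17 °C. Conversely 225 probes tested in the tail were not well above background on any body array, and 25 of them rose and 7 fell.

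A difference between the temperature responses of body and tail, tested within larvae, passed for 8 of 16617 probes with 7 distinct sequences (limma, adjusted p under 0.05), 3 with a more positive and 5 with a more negative change in the body; 2080 had an unadjusted p under 0.05. Of the 8, 6 passed for temperature in the tail and not in the body, and 5 were at least 2-fold higher in body than in tail. This division did not hold without warm replicate 3, where of 33 probes 11 passed in the tail only and 11 in the body only. KUST_47270_PI429357585, named above for the tail, had the largest fitted difference, 3.88 on the log2 scale (standard error 0.59, adjusted p = 0.0354). With its warm tails at their background limit and warm replicate 3 left out the difference was at least 3.27. Without that larva it also passed in the body (log2 fold change 0.92, adjusted p = 0.0142). KUST_28547_PI429357568 (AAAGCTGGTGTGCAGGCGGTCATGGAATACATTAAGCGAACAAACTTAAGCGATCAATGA; bases 244 to 1440 of comp386538_c0_seq1) fell from 0.75 ± 0.13 to -2.43 ± 0.31 in tails (SD, n = 6 each), with all 6 warm tails below every cold tail. In cold bodies it stood at 2.39 ± 0.91 (SD, n = 6), and the log2 difference of warm from cold bodies was -0.39 with a standard error of 0.39 (adjusted p = 0.532). The responses differed by 2.79 (standard error 0.40, adjusted p = 0.0328). KUST_8919_PI429357568 (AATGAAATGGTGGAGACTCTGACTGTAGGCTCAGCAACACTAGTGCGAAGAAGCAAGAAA; bases 123 to 503 of comp226088_c1_seq1) stood at 8.68 ± 0.39 and 8.52 ± 0.27 in cold and warm bodies and rose from -3.74 ± 0.84 to -1.34 ± 0.69 in tails (SD, n = 6 each), with 5 of 6 warm tails above every cold tail and a difference of -2.56 (standard error 0.41, adjusted p = 0.0493). KUST_35318_PI429357568 (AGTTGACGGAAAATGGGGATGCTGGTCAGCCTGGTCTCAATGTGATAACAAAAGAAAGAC; bases 426 to 2168 of comp403780_c0_seq1) rose from -3.27 ± 0.94 to -1.81 ± 0.55 in tails and stood at 3.62 ± 0.58 and 3.15 ± 0.44 in bodies (SD, n = 6 each), with 4 of 6 warm tails above every cold tail and a difference of -1.94 (standard error 0.28, adjusted p = 0.0328).

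The count of 8 changed with the normalisation and with single larvae. By limma no probe passed under quantile normalisation or under normexp with quantile normalisation, where 1954 and 2029 had an unadjusted p under 0.05 and the 4 named probes had adjusted p from 0.0599 to 0.132. In the order named their log2 differences were 3.29, 2.78, -2.66 and -1.87 under quantile normalisation, and 1.32, 1.91, -1.58 and -1.18 with normexp. Without a filter their adjusted p ran from 0.0212 to 0.0342. Without warm replicate 3 the differences were 3.92, 2.88, -2.63 and -1.75 (adjusted p = 0.0377, 0.0304, 0.0424 and 0.0304). Quantile normalisation without that larva, tried after the data were seen, gave 48 probes, the original 8 among them. With the slide as a further block 2 passed. The count was 0 without cold replicate 2, 4 or 5 or warm replicate 1 or 4 (limma; unadjusted p under 0.05 for 1584 to 1903 probes), 1 without cold replicate 7, and 2 without cold replicate 6 or warm replicate 7. It was 5 without warm replicate 6, 15 without cold replicate 8, 33 without warm replicate 3 and 39 without warm replicate 5. In 10 of the 12 larvae the deviations of the body array from its group mean correlated best with those of the tail array of the same label, with r from 0.27 to 0.63 across probes. The exceptions were warm replicates 5 and 6, whose own r was 0.05 and -0.13. The body labelled 5 correlated with the tail labelled 6 at r = 0.48, and the body labelled 6 with the tail labelled 5 at r = 0.63. With the tails of these larvae exchanged, which was tried after that was seen, 72 probes passed, 26 of them called in the tail only and 18 in the body only, and 204 passed without the dim array's larva.

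**Figure D4:**
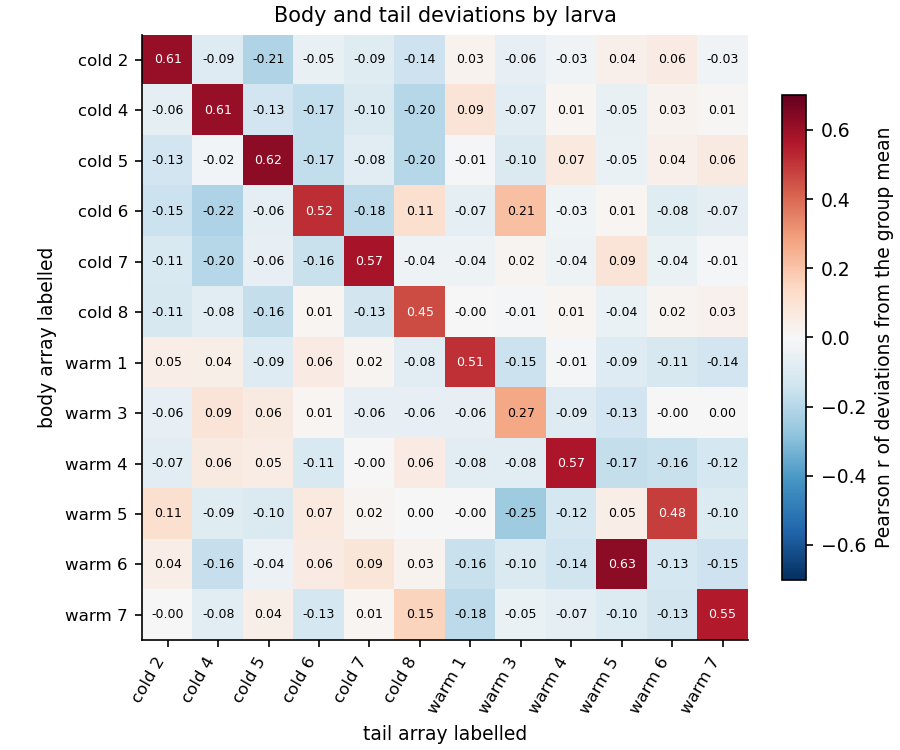
Pearson's r across 14807 probes between the deviations of each body array (rows) and each tail array (columns) from their group means. The diagonal, body and tail of the same label, is between 0.27 and 0.63 except at warm 5 (0.05) and warm 6 (-0.13), where the crossed pairs reach 0.48 and 0.63.

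Body and tail differed in 11475 of 16617 probes (limma within larvae, adjusted p under 0.05), 4292 higher in body and 7183 higher in tail, with 8573 distinct sequences in all. By size the order turned. At least 4-fold differences were found for 965 probes higher in body and 214 higher in tail. The largest fitted excess in the body was that of KUST_55964_PI429357585 (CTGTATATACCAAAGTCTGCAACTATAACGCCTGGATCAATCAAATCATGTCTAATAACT; bases 585 to 1343 of comp90583_c1_seq1), at 8.10 ± 0.48 in body and -6.23 ± 1.44 in tail (SD, n = 12 each), a log2 difference of 14.33 (adjusted p = 3.21e-13). It was well above background on only 3 of the 12 tail arrays, and with the others at their background limit the excess was at least 12.97. KUST_45635_PI429357568 (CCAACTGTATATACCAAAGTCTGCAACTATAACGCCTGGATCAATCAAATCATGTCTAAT; bases 340 to 1098 of comp420201_c4_seq3), whose sequence shares 56 bases with the former, was 14.32 higher in body on the log2 scale (adjusted p = 1.92e-13). It too was well above background on 3 of the 12 tail arrays, and its excess was at least 12.94.

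The largest fitted excess in the tail was that of KUST_45283_PI429357568 (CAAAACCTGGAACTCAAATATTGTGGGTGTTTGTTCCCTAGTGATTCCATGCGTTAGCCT; bases 824 to 2905 of comp419735_c0_seq9), at -3.28 ± 1.42 in body and 2.62 ± 0.36 in tail (SD, n = 12 each), a log2 difference of -5.90 (adjusted p = 2.2e-09). It was well above background on 8 of the 12 body arrays, and with the others at their limit the excess was at least 5.68. KUST_43402_PI429357585 (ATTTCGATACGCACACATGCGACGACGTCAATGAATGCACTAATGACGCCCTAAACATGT; bases 3 to 737 of comp53122_c0_seq1) stood at -3.74 ± 0.81 in body and 1.39 ± 0.70 in tail (SD, n = 12 each), a log2 difference of -5.13 (adjusted p = 5.97e-12). It was well above background on 10 of the 12 body arrays, and its excess was at least 4.89. All 4 probes, chosen as the largest differences over these larvae, had the same direction in 12 of 12 larvae. The share of calls higher in tail was 62.6%; it was 65.6% without the dim array's larva and 61.1% with each array centred on the median of the probes tested. Among the probes well above background on the 23 other arrays it was 66.6%. Within slides 1, 2 and 3, 99.02, 92.2 and 98.4% of the probes called on the other slides alone, without the larva block, had the same direction, and with the slide as a further block 11444 probes passed. The mean log2 levels of body and tail correlated at r = 0.86 across the 16617 probes.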

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

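The tests of the dim array and of the exchanged pair described here were chosen after the results were seen; those of the regrouped larvae and of the shared deviations of a larva's samples were not. In 80 groups of 6 values (20 of array measures and 60 of named probes) the highest or lowest sample stood apart from the rest in 14. A rate of 1 in 20 would give 4, but the groups are not independent. Several of the 14 came from the dim array, from both samples of cold larva 6 or from overlapping probes. The excess over 4 is therefore no test.

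The array of warm body replicate 3 stood apart in the share of spots well above background (28.8%, the nearest of its group 70.2%), the 75th percentile of the signal (15.9 against 283.5), the coefficient of variation of replicate spots (17.9 against 5.77%) and the median spike-in signal (86.7 against 946.5). Its spike-in controls, which are added to the RNA before labelling, lay 3.44 on the log2 scale below the lowest of the other 23 arrays, whose own range was 0.58, which argues for a loss of signal at or after labelling. A shortage of the larva's own RNA would leave the spike-ins in place and is excluded as the whole cause, since these were 10.8-fold below the lowest other array, although the ratio of the 75th percentile to the spike-in median was also lower (0.183 against 0.237 to 0.457). A tail sample under a body label is excluded as well: its lowest correlation with another body array was 0.92 and its highest with a tail array 0.82. The design gives no biological explanation for a single array of a group, and none was tested.

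The arrays of warm replicates 5 and 6 did not pair as labelled. Over 600 probes with a strong larva pattern in the other 10 larvae, the body labelled 5 correlated with the tail labelled 6, and the body labelled 6 with the tail labelled 5, at no less than r = 0.88, where 58 other pairs of different larvae reached at most 0.04. With slide means removed, these probes gave 0.36 for body 5 with tail 6 and 0.81 for body 6 with tail 5. The 58 other pairs then reached at most 0.25, and the lowest own pair of the other larvae was 0.63. Over all probes with slide means removed, the body labelled 6 and the tail labelled 5, from different slides, correlated at 0.60 against at most 0.12, which excludes slides for that pair; the body labelled 5 and the tail labelled 6, both on slide 1, fell from 0.48 to 0.24, below the lowest own pair of the other larvae (0.25), so that a part played by their shared slide stays open. A likeness of the larvae would leave their own pairs in place, but the higher of their own correlations over all probes was 0.0488, below the lowest of the other larvae (0.27). A candidate explanation is therefore that the labels of both larvae were exchanged in 1 of the tissues; which one cannot be seen, and the body and tail temperature comparisons are the same either way.

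The temperature responses of body and tail differed for 8 probes by the test of the difference itself. Among the named ones the response in body less that in tail was 3.88 for KUST_47270_PI429357585, 2.79 for KUST_28547_PI429357568, -2.56 for KUST_8919_PI429357568 and -1.94 for KUST_35318_PI429357568. Of 100 groupings of the larvae 1, the real one, gave as many, and the highest of the others gave 2, so that chance is an unlikely source of this count. The count was not stable, however. By limma it was 0 under quantile normalisation and in some of the fits that left out a single larva. Without the larva of the dim array it was 48 under quantile normalisation, so that the 0 there rested on that larva.

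For temperature in body the real grouping gave 2567 probes and the highest of 99 others 7, and in tail 3750 and 66. In each, 1 of 100 groupings, the real one, gave as many, so that chance is an unlikely source of these counts. For body against tail, 1 of 100 exchanges of the tissues within larvae, the real assignment, gave 11475 probes, and the highest of the others, 5148.

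Single samples stood apart for 7 named probes. For KUST_23171_PI429357585 these were cold body replicate 6 (-2.72, the nearest -0.06), cold tail replicate 6 (-2.26, the nearest 0.18) and warm tail replicate 7 (-0.70, the nearest -2.47). Warm body replicate 1 stood at 5.94 for KUST_44681_PI429357568, cold body replicate 2 at -1.96 for KUST_47270_PI429357585 and cold tail replicate 7 at -2.11 for KUST_8919_PI429357568. Warm tail replicate 3 stood at -4.74 for KUST_55964_PI429357585 and at -4.50 for KUST_45635_PI429357568, and cold tail replicate 4 at 1.91 for KUST_45283_PI429357568. The coefficient of variation of replicate spots was 6.25% on cold tail replicate 8, the nearest of its group 5.09%.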

How the results depend on the processing

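Alternatives that leave out the dim array together with another change, exchange tails, average identical sequences, centre the arrays, add the slide to the paired fits, or lower the floor of the value table were chosen after seeing the data. Leaving out each larva in turn gave 1977 to 3915 probes for temperature in body, 3105 to 3587 in tail, 0 to 39 for the difference of responses (limma; 1584 to 1903 with an unadjusted p under 0.05 where 0) and 10941 to 12908 for tissue. The correlation of the responses was then 0.65 to 0.74, and the recovery of body calls in tail 55.7 to 69.7%. In body, 1509 probes passed with the filter on every array, which left 5914 to test (3711 of 13846 without the dim array), and 4155 with array weights, where the dim array's weight was 0.084. The authors' value table gave 32, and 0 with a floor of 0.01 (limma; 867 with an unadjusted p under 0.05), but 3288 without the dim array, in whose column zeros are many. It also gave 5038 for tissue (10231 without that larva), a correlation of 0.37 and a recovery of 90.3% of only 31 body calls (0.74 and 57.8% without that larva). The larva number as a block gave 1072 in body and 1299 in tail; same-numbered cold and warm larvae correlated above 0.1 in 1 of 8 pairs, and in 2 of 8 best with their own number, so the numbers do not pair them. For the difference of responses, 3 probes passed without the larva block. None passed by limma under quantile normalisation, normexp with quantile normalisation or the value table, where 1954, 2029 and 506 had an unadjusted p under 0.05. There were 2 with the slide as a block, and without the dim array's larva 48 under quantile normalisation and 244 from the value table. With the tails of warm replicates 5 and 6 exchanged there were 72, and 204 without the dim array's larva, the original 8 among them both times. Without a filter the correlation of responses was 0.49. Over the 14909 filtered probes it was 0.44 with body and tail from different larvae, 3 cold and 3 warm for each tissue. From the same larvae at that smaller number it was 0.62. The cause of these changes was not tested where none is given. Of 48 alternative values of the named probes 37 stayed past the threshold, 11 did not and none changed sign. Of the 48, 16 came from leaving out the filter, which does not alter a probe's fold change, so that their sign and size were fixed in advance. All 11 losses came under the other normalisations. They included every such value of the probes named for the difference of responses. Normexp with quantile normalisation shrank 11 of its 16 values by over 1.5 times, to as little as 0.28 of the reported log2 size; quantile normalisation alone and no filter did so for none of 16 each. The other counts stayed within 1.5 times. Gene-list alternatives were not run, as the files pair no probes with gene names. Signal over background limits the dim array and the 5528 probes not tested in either tissue.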

Other observations

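The tests of the larva pattern described here were planned before their values were seen. Apart from temperature and tissue, the larvae differed from each other in ways that both of their samples shared. Of 14807 probes, 394 (2.66%) had deviations from the group means that correlated above 0.8 between body and tail over 11 larvae, with an SD above 0.5 on the log2 scale, and 34 of the 394 were called for temperature in body or tail. Among all probes tested in both tissues, 16.7% were called in body and 24.4% in tail. A large spread within groups makes a call less likely, so the 34 say nothing on how larva patterns relate to temperature. The 11 larvae left out warm replicate 3 and held warm replicates 5 and 6 as labelled. Over the 10 larvae other than those 2, a set chosen after their crossed pairing was seen, 600 probes met these limits. KUST_23171_PI429357585, among the largest falls at 17 °C in both tissues, was low in both samples of cold larva 6 and high in both samples of warm larva 7 (-1.06 in body and -0.70 in tail).

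The body and tail arrays of each labelled larva lay on different slides, so a slide common to both could not cause this sharing. Removing slide means was therefore no test of that cause. With them removed, the mean correlation of a larva's own body and tail deviations was 0.37, and the highest over 100 pairings of different larvae was 0.04. Differences between individual larvae in their RNA may contribute, as the mean own correlation was 0.43 before slides were removed. Bases in a larva that differ from the probe sequence would lower the signal of the same probe in both samples and stay open for part of the pattern. Probes of another sequence on the same contig component correlated over larvae with a median of 0.33 (347 pairs, bootstrap interval 0.27 to 0.44). The median was 0.015 for random pairs and 0.96 for the same sequence under another ID (3863 pairs). Other sequences of a component thus shared part of the pattern. How much of it is tied to single probe sequences is not decided by these values.

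Contig components with several called sequences mostly moved one way. In tail, 34 of 40 such components had all their calls in the same direction and 6 had calls in opposite directions; in body these were 10 and 4 of 14. The fold change in body was related to the mean level of the probe (Spearman's rho = -0.27 across probes), but not without the larva of the dim array (rho = -0.024), so that the relation rested on that larva. In tail rho was -0.03. The coding length of the reading frame was related to the difference between tissues at rho = -0.20.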
